A study of Homo sapiens with 5 samples.

How the data were processed

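Messenger RNA was measured in 5 libraries of WSU-FSCCL, a human B-cell line derived from a follicular lymphoma. Per the labels' protocols, the line stably expressed the nuclease Cas9 and received a lentiviral construct that carries mCherry and a pair of guide RNAs, one against the switch region of the IgM gene and one against that of the IgG4 gene. Cells positive for mCherry and for surface IgM or surface IgG were then collected by flow cytometry. Stranded libraries were made from polyadenylated RNA with a KAPA kit, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, Salmon and the genome build GRCh38, without versions, and how reads shared between near-identical genes were divided is not given in the sources used here.

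The deposited table holds 43301 genes by symbol and log2 values that the authors normalized. The labels call them log2 normalized counts. Their form was read from the values: each is a variance-stabilizing transform of whole reads divided by 1 size factor per library, with a gene-specific shift that is shared by the 5 libraries and so leaves differences between them untouched. The most common value, that of genes with no reads, was 7.84. Whole reads were recovered from the values by solving that transform for each of the 22138 genes that vary between the 5 libraries. All values of 100.0% of these genes came out whole within a tolerance of 0.0001 reads, with a largest distance of 1.1e-07 reads, and 2 genes had more than 1 solution. The remaining 21163 genes had equal values in the 5 libraries and were taken as 0 reads. The recovery code was tested on 4000 simulated genes and returned 100.0% of them exactly. Normalized reads in the text are these recovered reads divided by the recovered size factors, which lay between 0.833 and 1.175. A deposited log2 difference understates the change of low genes: a 2-fold change came to 0.37 from 100 to 200 normalized reads and to 0.78 from 1000 to 2000. Log2 differences and their tests are on the deposited scale unless another scale is named, and folds are ratios of mean normalized reads.

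Samples were grouped by title into 2 IgM and 3 IgG4 libraries. The second sort label of IgG4 replicates 2 and 3 reads surface IgM, against their titles, and IGHM and IGHG4 are therefore given in each library. The table's columns name the IgG libraries IgG1, while the titles say IgG4; columns were matched to samples by class and replicate number. Of 7 columns of values, 2 had no matching sample and were not used. The series' design text says that samples were removed because of a batch effect. Nothing in the labels says that replicates came from separate cultures or sorts, so p-values measure the spread between these libraries only, which may be technical.

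The comparison of IgG4 with IgM used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The planned filter was a mean of at least 10 normalized counts, written as a log2 value of 3.46. That number lies below the level of genes with no reads and would have removed nothing, so the mean value had to reach that of 10 normalized reads on the deposited scale, 8.14 for a gene at the most common level without reads. Because of the gene-specific shift this is not the same number of reads for each gene: JCHAIN, with fewer reads on average than IGHA1, was tested and IGHA1 was not. This was set after the scale was seen and before any test, and left 14005 genes. The number as written is the same as no filter and appears among the alternatives. The test was run on simulated counts with known changes for this comparison, over 14005 genes: it called 83.6% of 67 genes changed 1.5-fold, 95.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 5.1% of its calls were false. Changes were planted only in genes with a mean of at least 50 normalized reads. The simulated counts were drawn independently, with no library that stands apart, so these rates need not hold for the deposited libraries. Replicates of a group were compared by a chi-square test of their counts, and every pair differed by more than sampling noise.

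Gene lists were fixed before the data were examined, as were the groups, the test, the rule for named genes and all alternatives not described as added. Lists with at least 5 tested members were tested with camera (correlation between genes preset at 0.01), camera with an estimated correlation, and fry. With an estimated correlation camera rests on the 3 residual degrees of freedom of the 5 libraries and not on the number of genes. It therefore had little power, and a call lost there neither shows nor excludes that correlation between genes had produced it. The text names every immunoglobulin heavy chain constant gene and JCHAIN, the 12 genes with the largest difference in each direction among those past the threshold with fully separated groups, the members with the smallest p of each list (up to 4 where camera passed, otherwise up to 2 that passed), and genes set in advance, with a few of these results left out of the text; any other gene is said to have been chosen after its values were seen. Under that rule variable genes, pseudogenes and unnamed loci stay out of the 12, and a gene's mean deposited value in the higher group, shift included, had to lie 2 log2 units above the filter. Of all symbols, 97.8% had a row in the RefSeq gene table, from which GRCh38 coordinates were taken. Another symbol than the listed one was used for 15 list members, the mitochondrial mRNAs among them. The alternatives were limma without the trend, with robust empirical Bayes or with library weights, no filter, a filter 3 log2 units higher, a further pseudocount of 10, quantile normalization, centring on medians, the replicate number as a block, only libraries whose labels agree, and each library left out in turn. limma-voom on the recovered reads was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

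Recovered totals were 39747151 and 42947512 reads in the IgM libraries and 44762236, 37642380 and 53162942 in IgG4 replicates 1, 2 and 3. An observed 0 allows up to 3 reads, which is 2.55 to 3.6 normalized reads depending on the library. Intervals and floors are at 95% and cover counting error only. Salmon, named above, reports estimated read numbers, so the recovered whole numbers may be rounded estimates. A recovered 0 need not mean that no read was present, and the intervals do not cover errors of assignment.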

Results

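RNA was sequenced from WSU-FSCCL follicular lymphoma cells after Cas9 had been directed to the switch regions of the IgM and IgG4 heavy chain genes. Switch regions are the repeats at which B cells exchange the constant part of their antibody, and joining the 2 cut sites places IGHG4 next to the variable region. Cells that kept IgM on their surface (2 libraries) were compared with cells that carried IgG (3 libraries, titled IgG4). The series asks what a change of receptor class does to such cells. Receptor class and sort gate change together between the groups. Differences outside the heavy chain locus therefore cannot be assigned to the class rather than to the sort or the handling of sorted cells. Depth ranged from 37642380 to 53162942 recovered reads per library.

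The switch was visible at the heavy chain locus on chromosome 14. IGHM (gene ID 3507, 105851966 to 105856217 of GRCh38), the constant gene of IgM, had 70448 ± 569.9 normalized reads in IgM cells (SD, n = 2) and 357.8 ± 259 in IgG4 cells (SD, n = 3), 197-fold less. IGHG4 (gene ID 3503, 105624476 to 105626065) rose from 24.9 ± 14.7 to 24907 ± 1337.8 normalized reads. IGHD (105838401 to 105845677), which is transcribed together with IGHM, fell from 8308 ± 307.7 to 24.1 ± 22.4 normalized reads. On the deposited scale the differences were -6.71 (SE 0.37) for IGHM, 6.33 (SE 0.08) for IGHG4 and -4.88 (SE 0.18) for IGHD, with limma adjusted p-values of 0.001, 6.6e-07 and 2.7e-04. Library by library, IGHG4 stood at 35.28 and 14.46 normalized reads in IgM replicates 1 and 2 and at 25070, 26160 and 23500 in IgG4 replicates 1, 2 and 3, and IGHM at 70050 and 70850 against 502.3, 58.85 and 512.3. The values of IgG4 replicates 2 and 3 therefore follow their titles and not the sort label that reads surface IgM.

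The other heavy chain constant genes did not move as 1 block. IGHG3 rose 4.08-fold (to 5651 ± 278.5 normalized reads, adjusted p = 1.3e-04), IGHG2 rose 11.3-fold (to 1106 ± 205.6, adjusted p = 0.001) and IGHG1 rose 1.63-fold (to 8241 ± 167.8, adjusted p = 0.003), although the 3 genes lie between the cut sites. The IGHG genes are near-identical, so the split of reads among them is uncertain. The pseudogene IGHGP, in the same stretch, had 141.9 ± 2.02 and 141.2 ± 21.1 normalized reads (difference -0.01, SE 0.06, adjusted p = 0.979), and the sign of that difference depended on the setting. IGHA1 had 16.9 ± 6.76 and 6.16 ± 4.93 normalized reads and lay below the filter. IGHE and IGHEP1 had 0 reads in each library, and IGHA2 had 1 read in IgG4 replicate 3 and 0 in the other 4 libraries. JCHAIN, which joins IgM pentamers, had 7.92 ± 3.41 and 10.3 ± 4.23 normalized reads (adjusted p = 0.831). Of the 8 constant genes between the cuts, 6 were tested, with 3 higher and 2 lower, also when adjusted over the list alone. The median difference of that list was 0.33 and its mean -1.23, opposite in sign, and camera did not pass (adjusted p = 0.347). The list of constant genes at or beyond the second cut had 1 tested member, IGHG4.

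**Figure D1:**
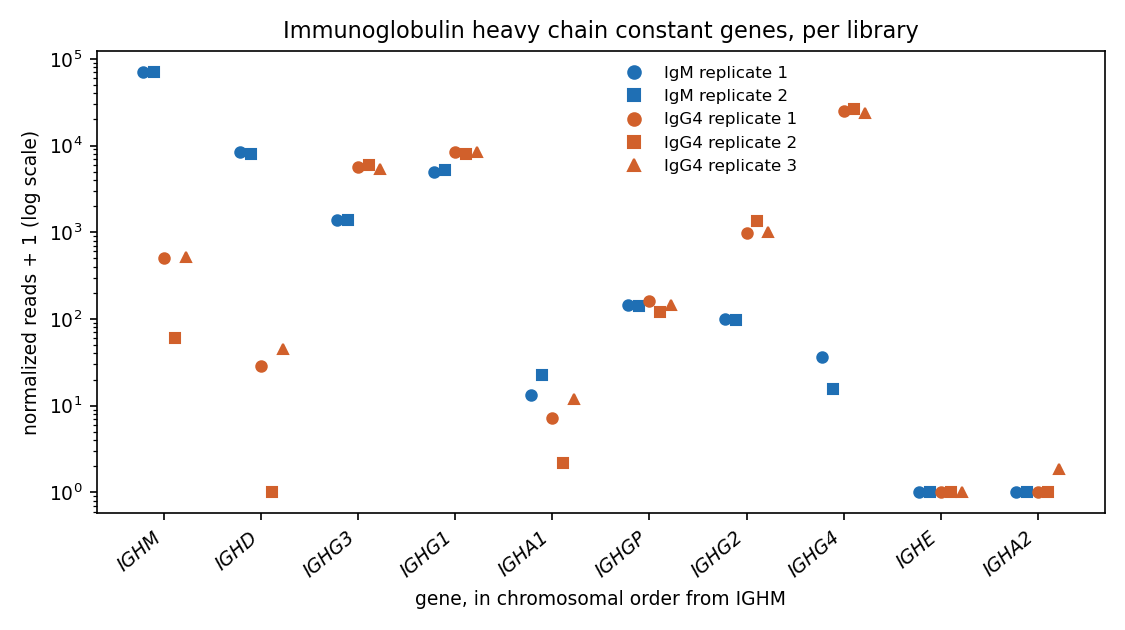
Normalized reads plus 1 (log axis) of each heavy chain constant gene in each of the 5 libraries, in chromosomal order from IGHM, with IgM libraries in blue and IgG4 libraries in orange. IGHM and IGHD are high in the IgM libraries, IGHG4 is high in the IgG4 libraries, and IGHGP lies near 141 in both groups; IGHEP1, at 0 in each library, is left out.

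Outside the heavy chain constant genes, the rule for named genes ranked genes whose deposited value lay well above the filter by their difference on that scale, which is not the order of the folds. By that rank the first to rise in IgG4 cells were DEPP1 (4.38-fold, from 677.3 ± 1.07 to 2963 ± 226.4 normalized reads, adjusted p = 2.7e-04), a regulator of autophagy, RAG1 (2.66-fold, from 5582 ± 301.1 to 14824 ± 3437.8, adjusted p = 0.022), the recombinase of antigen receptor gene assembly, and MAN1A1 (2.91-fold, from 1181 ± 65 to 3439 ± 64.4, adjusted p = 2.7e-04), a mannosidase that trims N-glycans in the Golgi. LGR6 (6.88-fold), TNFRSF19 (2.66-fold), the lambda light chain constant gene IGLC3 (2.40-fold), the cell cycle kinase gene CDK6 (2.14-fold) and PHLDB2 (2.20-fold) rose as well, with adjusted p-values between 9.4e-04 and 0.046. By the same rank the first to fall were COL5A1 (4.12-fold, from 1788 ± 75.7 to 433.4 ± 98, adjusted p = 0.003), a collagen chain gene, and UBASH3B (2.14-fold, from 7100 ± 136.4 to 3319 ± 29.3, adjusted p = 3.1e-04), whose product is a phosphatase of SYK-family kinases. FUT7 (2.22-fold), a fucosyltransferase gene of selectin ligand synthesis, NOG (2.62-fold), SDK2 (2.47-fold), the long non-coding RNA FAM30A (2.09-fold), which lies on chromosome 14 at 105917979 to 105932642, near IGHM, the cyclin gene CCND3 (1.93-fold), the immediate early gene IER2 (1.95-fold), the transcription factor gene LYL1 (1.85-fold) and ZFP36L1 (1.84-fold), which encodes a factor of mRNA decay, fell with adjusted p-values between 4.3e-04 and 0.024. The rule required each of these genes to have its 3 IgG4 libraries on one side of both IgM libraries.

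In all, 155 of 14005 genes passed an adjusted p of 0.05 in limma, 50 higher and 105 lower in IgG4. On the deposited scale 17 of them differed more than 2-fold (11 higher, 6 lower), and in normalized reads 57 did (23 higher, 34 lower). The 155 genes all had fully separated groups, as had 34.9% of the tested genes, against 20% by chance for 2 libraries against 3. The counts depended on each library: without IgG4 replicate 2, which stood apart, 3065 genes passed (1763 higher, 1302 lower), the 155 among them and in the same direction, and with IgM replicate 1, IgM replicate 2, IgG4 replicate 1 or IgG4 replicate 3 left out in turn 12, 16, 59 and 36 genes passed. The genes that passed without IgG4 replicate 2 had a median absolute log2 difference of 0.2, against 0.52 for the 155. That library was singled out by its values and not by a label. Leaving it out lowers the spread within IgG4, so p-values given without it, here and below, are likely too small. With library weights 4482 genes passed. The weights were 0.574, 0.145 and 7.58 for IgG4 replicates 1, 2 and 3 and 1.259 for each IgM library, so the IgG4 group rested mainly on replicate 3.

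**Figure D2:**
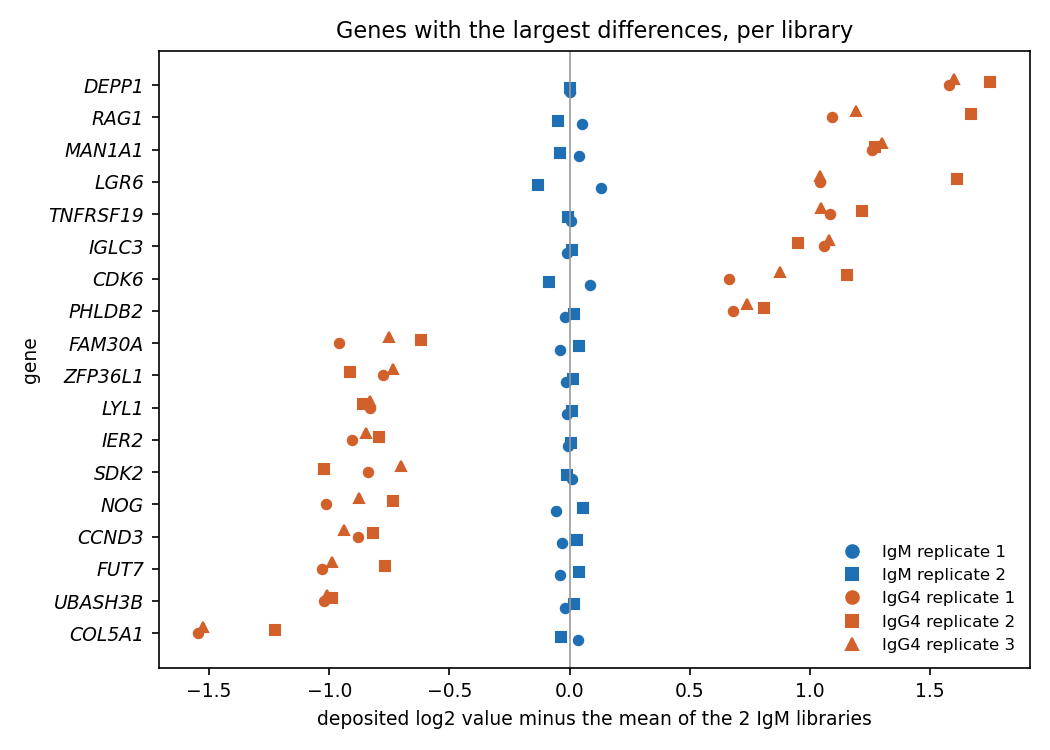
Deposited log2 value of each library minus the mean of the 2 IgM libraries, for the 18 genes outside the heavy chain constant genes that the rule for named genes ranked first in each direction. The rule left out genes whose higher group lay less than 2 log2 units above the filter, such as TNF (difference -1.04). As the rule required, the 3 IgG4 libraries (orange) lie on one side of both IgM libraries (blue) for each gene, from COL5A1 (difference -1.43) to DEPP1 (1.65).

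Components of B-cell receptor signalling moved in both directions. Of 36 tested members, 2 were higher and 3 lower (4 higher and 7 lower adjusted over the list alone). The receptor-proximal kinase genes SYK (1.46-fold, from 7025 ± 58.5 to 10284 ± 627.6 normalized reads, adjusted p = 0.015) and BTK (1.30-fold, adjusted p = 0.022) were higher. PTPN6, the gene of the inhibitory phosphatase SHP-1, was 1.62-fold lower (from 4352 ± 39.9 to 2679 ± 151.4, adjusted p = 0.006), CD81 was 1.26-fold lower (adjusted p = 0.026), and the fifth member, CD72, named after its value was seen, had a difference of -0.40 (adjusted p = 0.029). The list as a whole was lower by camera (median difference -0.06, adjusted p = 0.048). That call was lost with an estimated correlation (adjusted p = 0.424 with an estimated correlation) and without IgG4 replicate 2 (adjusted p = 0.058). The receptor's signalling chains did not pass: CD79A had 24495 ± 1593.1 and 20196 ± 3162.1 normalized reads (adjusted p = 0.393) and CD79B 34036 ± 751.9 and 38393 ± 1354.7 (adjusted p = 0.211). Without IgG4 replicate 2 the 2 genes passed in limma, with adjusted p-values of 0.046 and 0.004.

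Early response genes, which B cells switch on within minutes of receptor or growth signals, were lower as a list. Of 30 tested members 4 were lower and 2 higher, or 12 lower and 3 higher adjusted over the list alone (median difference -0.08, camera adjusted p = 2.9e-04, fry adjusted p = 2.1e-04). The camera call was lost with an estimated correlation (adjusted p = 0.42 with an estimated correlation). EGR1 fell from 374.9 ± 1.45 to 153.7 ± 35.5 normalized reads (2.44-fold, adjusted p = 0.032), JUNB fell 1.47-fold (adjusted p = 0.014), and IER2 and ZFP36L1 are given with the ranked genes above. The antiproliferative gene BTG2 rose 1.59-fold (adjusted p = 0.035), and RGS1, named after its value was seen, had a difference of 0.40 (adjusted p = 0.046). MYC had 20001 ± 410.3 and 19101 ± 83.6 normalized reads (adjusted p = 0.511) and CD69 79.8 ± 8.39 and 49 ± 10.4 (adjusted p = 0.286). Of 22 tested NF-kB targets 3 were lower and 1 higher (2 higher and 4 lower adjusted over the list alone), and camera did not pass (adjusted p = 0.087). Without IgG4 replicate 2 it passed, with 8 members lower and 3 higher (camera adjusted p = 0.030, or adjusted p = 0.416 with an estimated correlation). The cytokine gene TNF fell from 590.7 ± 8.96 to 135.6 ± 37.5 normalized reads (4.36-fold, adjusted p = 0.006), RELB and LTB, named after their values were seen, had differences of -0.44 and -0.42, and IRF4, a transcription factor gene of late B-cell stages, rose 1.38-fold (adjusted p = 0.010).

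Germinal-centre identity genes were lower as a list, with 2 of 23 tested members lower and 0 higher (7 lower and 1 higher adjusted over the list alone, median difference -0.17, camera adjusted p = 0.011). The call was lost with an estimated correlation (adjusted p = 0.42 with an estimated correlation), and without IgG4 replicate 2 the median shrank to -0.08 (camera adjusted p = 0.018). NEIL1, a DNA glycosylase gene, fell 2.51-fold (from 779.1 ± 47.8 to 310.7 ± 37.7 normalized reads, adjusted p = 0.007) and the migration receptor gene P2RY8 fell 1.35-fold (adjusted p = 0.032). ELL3 had 344.4 ± 28.6 and 196.9 ± 23.8 normalized reads (adjusted p = 0.066) and MME 6552 ± 173.9 and 8230.5 ± 439.6 (adjusted p = 0.067). BCL6, the master regulator of the germinal centre, had 1020.1 ± 189 and 421.5 ± 263.4 (adjusted p = 0.294). The lowest value was that of IgG4 replicate 2 (133.3 normalized reads), and without that library the difference was -0.57 (adjusted p = 0.002). CXCR4, the chemokine receptor of the dark zone, rose 1.59-fold (from 9700.5 ± 352.9 to 15434 ± 1480.6, adjusted p = 0.022) and was the 1 of 11 dark-zone and light-zone genes that passed (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.64). Among 18 plasma-cell genes IRF4 was higher and 0 were lower (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.705). CD38 had 11187 ± 49.8 and 9419 ± 523.4 normalized reads (adjusted p = 0.128), PRDM1 92 ± 13.1 and 105.7 ± 43.1 (adjusted p = 0.889) and XBP1 2677 ± 51.8 and 3155 ± 530.2 (adjusted p = 0.522). BCL2 had 9632 ± 273 and 9149 ± 710.8 normalized reads (adjusted p = 0.663). Without IgG4 replicate 2 the plasma-cell list had 6 members higher and 1 lower (camera adjusted p = 0.039, or adjusted p = 0.416 with an estimated correlation). In limma, ELL3, MME, CD38, XBP1 and BCL2 then passed (adjusted p = 0.002, 4.2e-04, 1.3e-04, 9.5e-05 and 0.015), and PRDM1 did not (adjusted p = 0.092).

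Light chain, surrogate light chain and J chain genes were higher as a list, with 2 of 10 tested members higher and 0 lower, also adjusted over the list alone (median difference 0.09, camera adjusted p = 0.003, fry adjusted p = 0.032). The camera call was lost with an estimated correlation (adjusted p = 0.42 with an estimated correlation). The members that passed were IGLC3 and the kappa constant gene IGKC (1.26-fold, from 11172 ± 22.7 to 14077.5 ± 266.9 normalized reads, adjusted p = 0.021). VPREB3 and IGLL1 did not pass, with differences of 0.08 and 0.29. IGLL1 had a smaller difference, 0.12, without IgG4 replicate 2 and passed there (limma adjusted p = 0.036).

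Camera called 6 further lists in which at most 1 gene passed on its own. Replication-dependent histone genes were higher (median difference 0.13 over 29 members, adjusted p = 6.1e-07, or adjusted p = 0.424 with an estimated correlation), with H3C2, H2BC17, H1-5 and H2BC5 at differences between 0.20 and 0.23. These mRNAs mostly lack a poly(A) tail, and the libraries were made from polyadenylated RNA. Genes of ribosome biogenesis and MYC targets were higher (median difference 0.13 over 37 members, adjusted p = 0.001, or adjusted p = 0.686 with an estimated correlation), with NPM1, UTP20, GNL3 and RRP9 at 0.17, 0.32, 0.16 and 0.23, as were cytosolic ribosomal proteins (median difference 0.07 over 36 members, adjusted p = 0.001, or adjusted p = 0.686 with an estimated correlation), with RPL7, RPLP0, RPL11 and RPS23 at 0.14, 0.15, 0.10 and 0.13. Without IgG4 replicate 2 the ribosomal protein call was lost (adjusted p = 0.075), while 31 of the 37 MYC targets were higher and 1 lower, with a median of 0.20. Cholesterol synthesis genes were lower (median difference -0.11 over 23 members, adjusted p = 2.2e-04, or adjusted p = 0.686 with an estimated correlation), with DHCR7, TM7SF2 and MSMO1 at -0.46, -0.30 and -0.23. The median of this list shrank to -0.05 without IgG4 replicate 2 (adjusted p = 0.030). Glycolysis and hypoxia genes were lower (median difference -0.06 over 29 members, adjusted p = 0.019, or adjusted p = 0.686 with an estimated correlation). The lactate exporter gene SLC16A3 was their 1 member that passed (2.07-fold lower, adjusted p = 0.019), and PFKFB4, PDK1 and ALDOC had differences of -0.58, -0.28 and -0.58. The sign of this list depended on IgG4 replicate 2: without it the median difference was 0.06 (11 members higher, 6 lower, camera adjusted p = 0.638), and with library weights, which count it least, it was 0.04. PFKFB4, PDK1 and ALDOC stayed lower without it, at -0.42, -0.18 and -0.34, and passed (limma adjusted p = 2.0e-04, 0.007 and 0.002). The camera call was also lost without IgM replicate 2 (adjusted p = 0.115). Mitochondrial mRNAs were lower (median difference -0.15 over 13 members, adjusted p = 0.014, or adjusted p = 0.686 with an estimated correlation), with COX2, COX1, ND4 and ND4L at -0.28, -0.22, -0.21 and -0.22. Their share of reads was 1.89% and 2.34% in IgM replicates 1 and 2 and 1.68%, 1.90% and 1.80% in IgG4 replicates 1 to 3, and without IgM replicate 2 the median was 0.03, with the opposite sign.

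The histone, ribosome biogenesis, ribosomal protein, cholesterol and mitochondrial lists had 0 members past the threshold in limma, over all genes or adjusted over the list alone, and 0 in limma-voom, while 12, 7, 2, 5 and 2 members had an unadjusted p below 0.05. With IgG4 replicate 2 left out, 4 of 29 histone genes and 3 of 36 ribosomal protein genes were higher. In the same setting 7 of 23 cholesterol genes and 4 of 13 mitochondrial mRNAs were lower, while 3065 of all 14005 tested genes passed. With an estimated correlation 0 of 28 lists passed camera (lowest camera adjusted p = 0.42), and 3 had an unadjusted p below 0.05. The estimated correlations of the early response, light chain, germinal-centre identity and B-cell receptor lists were -0.032, -0.042, -0.027 and -0.005. Being negative, they cannot be why those calls were lost. In the other called lists the estimates lay between 0.173 and 0.798, far above the preset 0.01. On these estimates the preset makes the camera p-values of those lists too small, and none of them passed fry. By fry 4 lists passed: the light chain, early response and germinal-centre identity lists, and the constant genes between the cuts (adjusted p = 0.0225). The glycolysis and hypoxia list had 4 members with an unadjusted p below 0.05, all lower.

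In the remaining lists few genes passed. MAN1A1 was the 1 member higher of 22 N-glycan genes (camera adjusted p = 0.087), in which the sialyltransferase gene ST6GAL1 had 4719 ± 150.5 and 5017 ± 263.6 normalized reads (adjusted p = 0.558). RAG1 was the 1 member higher of 21 FOXO1 and KLF2 targets (camera adjusted p = 0.547), and SYVN1, a ubiquitin ligase gene of the endoplasmic reticulum, was the 1 lower of 26 genes of the unfolded protein response (1.22-fold, adjusted p = 0.036, list adjusted p = 0.2). Without IgG4 replicate 2 the last list had 16 members higher and 2 lower (camera adjusted p = 2.6e-09, adjusted p = 0.416 with an estimated correlation). The N-glycan and oxidative phosphorylation lists then passed camera (adjusted p = 0.039 each, or adjusted p = 0.416 and 0.62 with an estimated correlation). Of 23 adhesion and migration receptors 2 were higher (CXCR4, and the tetraspanin gene CD9 at 2.67-fold, adjusted p = 0.011) and 2 lower (P2RY8, and ITGA4, named after its value was seen, with a difference of -0.41), with 4 higher and 7 lower adjusted over the list alone and a camera adjusted p of 0.457. The memory B-cell (10 tested), interferon (33), MHC class II (7), MHC class I (14), oxidative phosphorylation (35), S-phase (30), G2 and mitosis (31), BCL2 family (22) and heat-shock (15) lists had 0 members past the threshold in limma over all genes and 0 in limma-voom, with 2, 10, 1, 2, 2, 2, 4, 2 and 5 at an unadjusted p below 0.05, and camera adjusted p-values between 0.168 and 0.705. Adjusted over the list alone, 1 interferon gene was lower, and 1 heat-shock gene was higher and 3 lower. With IgG4 replicate 2 left out, the members higher and lower were 1 and 3 (memory B-cell), 3 and 4 (interferon), 1 and 2 (MHC class II), 2 and 3 (MHC class I), 7 and 1 (oxidative phosphorylation), 5 and 2 (S-phase), 2 and 8 (G2 and mitosis), 6 and 3 (BCL2 family) and 7 and 3 (heat-shock). In that setting 3065 of all 14005 tested genes passed, so counts near that share are not particular to a list.

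Markers of other cells were mostly under the filter. Of 17 T-cell and natural killer markers 2 were tested, and TRAC, the T-cell receptor alpha constant gene, was 3.81-fold lower in IgG4 (from 165.5 ± 15.7 to 43.4 ± 15.8 normalized reads, adjusted p = 0.025). Of 17 myeloid and 17 fibroblast, endothelial and epithelial markers 4 and 3 were tested, and 0 passed in limma or limma-voom, with 0 and 1 at an unadjusted p below 0.05 (1 fibroblast marker was higher adjusted over the list alone).

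**Figure D3:**
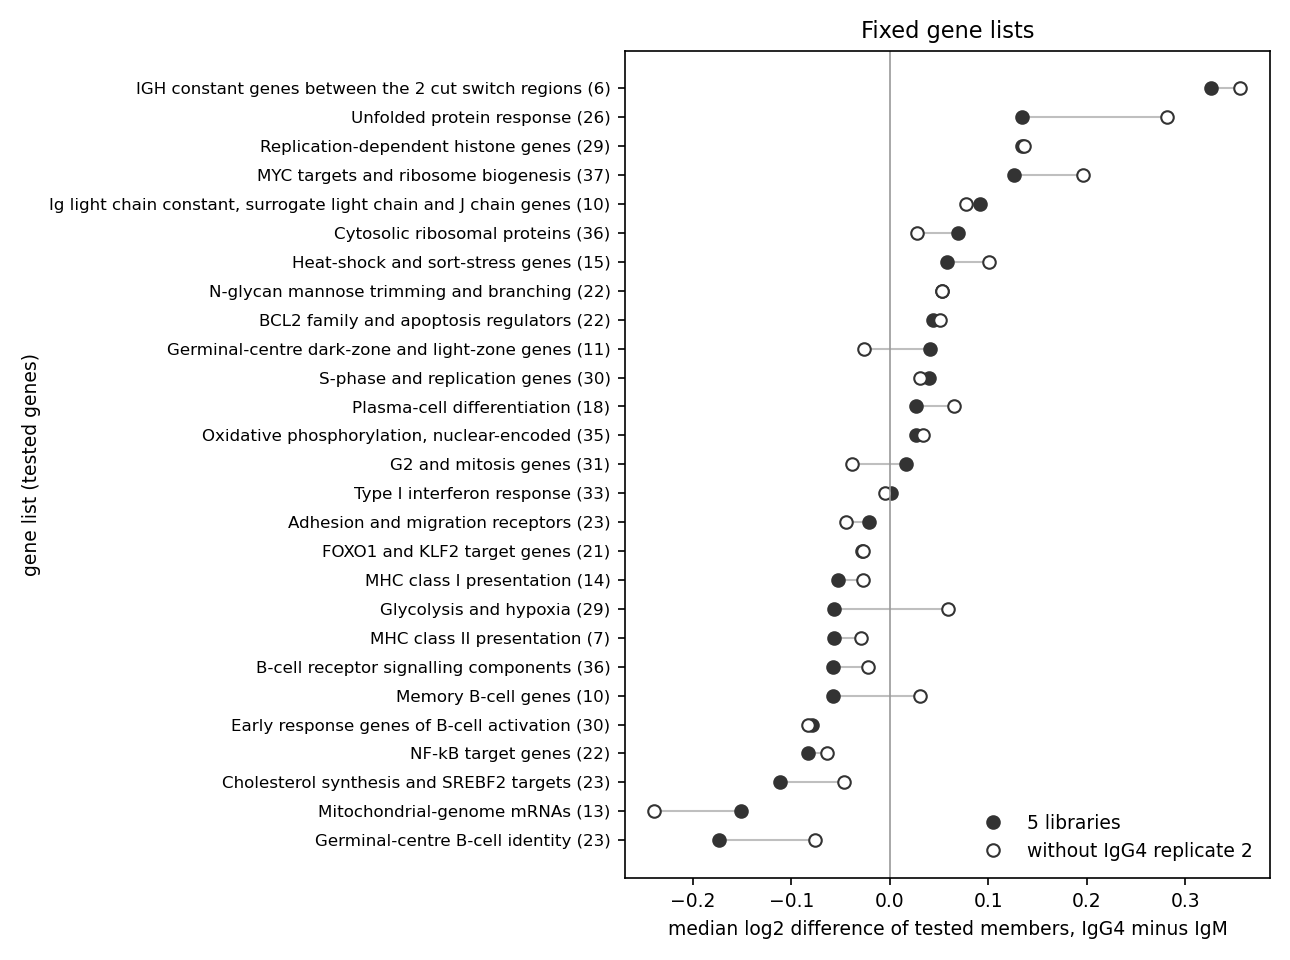
Median log2 difference (IgG4 minus IgM, deposited scale) of the tested members of 27 of the 28 lists with at least 5, over the 5 libraries (filled) and without IgG4 replicate 2 (open); the number of tested members is in parentheses. Glycolysis moves from -0.06 to 0.06 and the unfolded protein response from 0.13 to 0.28, while the early response median stays at -0.08.

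The libraries separated by group on the first principal component, which held 50.5% of the variance: the IgM libraries lay at -11.42 and -11.82 and the IgG4 libraries at 7.15, 9.45 and 6.64. The second component, with 36.6%, set IgG4 replicate 2 (13.92) apart from IgG4 replicates 1 (-9.64) and 3 (-6.18). Among genes with a mean of at least 50 recovered reads, not normalized, over the 2 libraries compared, 306 differed more than 2-fold between IgG4 replicates 1 and 2. Between IgG4 replicates 2 and 3 it was 224, against 36 between 1 and 3 and 40 between the IgM replicates.

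**Figure D4:**
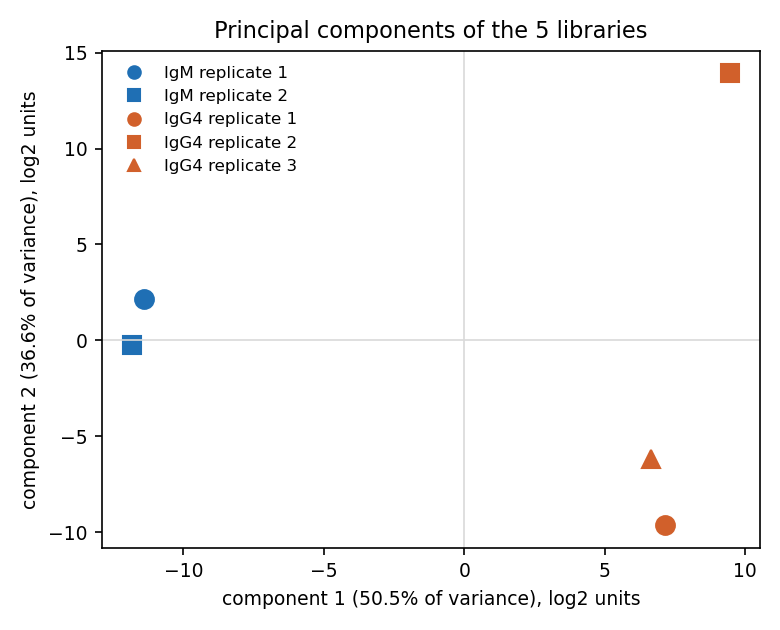
First and second principal components of the centred deposited log2 values of the tested genes, with 1 point per library (IgM blue, IgG4 orange). The groups part along component 1, and IgG4 replicate 2, at 13.92 on component 2, lies away from IgG4 replicates 1 and 3.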

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

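limma-voom on the recovered reads, with and without IgG4 replicate 2, was chosen after seeing the data; the other alternatives were set before. Planned count models of another kind were not run, and limma-voom stands in their place. IGHM and IGHG4 kept their direction and passed under all 17 alternatives (IGHM from -8.00 to -6.29, IGHG4 from 6.23 to 10.08). Across the alternatives, the other named genes and called lists kept direction and side of the threshold in 1221 cases, newly passed in 114, no longer passed in 133 and changed sign in 13. With library weights 4482 genes passed (2486 higher, 1996 lower) and with only the libraries whose labels agree 2583 (1493 higher, 1090 lower). The library weights put IgG4 replicate 3 (7.58) far above IgG4 replicates 1 and 2 (0.574 and 0.145). The stricter filter tested 5100 genes and passed 70 (25 higher, 45 lower, 8 over 2-fold). Leaving out 1 library gave 12 to 3065 genes, 7 to 1763 higher, 5 to 1302 lower and 11 to 21 over 2-fold; an arm left with 1 library was assumed to vary like the other. limma-voom gave 56 genes over 2-fold, on a scale that does not compress low genes, and shared 149 of its 161 calls; without IgG4 replicate 2 it gave 2931 (1674 higher, 1257 lower, 230 over 2-fold). Camera with an estimated correlation passed 0 lists. The replicate block passed 42 genes (13 higher, 29 lower), all among the 155. The replicate numbers pair only 2 samples per group. Deviations of same-numbered samples from their group means had correlations of -0.222 and -0.167. With 2 IgM libraries those deviations are mirror images of each other, so the correlations cannot decide whether equal numbers mark a pair. IGHGP, at -0.005, changed sign with library weights (0.010), quantile normalization (0.033), agreeing labels (0.068), without IgM replicate 1 (0.000), without IgG4 replicate 2 (0.038) and in limma-voom without it (0.092); with 1 library left out it ranged from -0.041 to 0.038. JCHAIN changed sign without IgM replicate 1 (range -0.005 to 0.077) and PRDM1 without IgG4 replicate 1 (range -0.032 to 0.162). The glycolysis list changed sign with library weights (0.036), agreeing labels (0.084), without IgG4 replicate 2 (range -0.159 to 0.059) and in limma-voom without it (0.064), and the mitochondrial list without IgM replicate 2 (range -0.336 to 0.026). Apart from fewer genes or libraries tested, the cause was not tested. IGHE and IGHEP1 had 0 reads in each library and IGHA2 had 1 read in IgG4 replicate 3 only, and an observed 0 allows up to 3 reads in a library.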

Other observations

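The tests of IgG4 replicate 2, of the IGHM reads left in IgG4 cells and, in its final form, of the IGHG genes were chosen after the results were seen, and the genes named below lie outside the rule for named genes and were chosen after their values were seen. Reads from lambda light chain variable genes summed to 2077 and 2204 normalized reads in the IgM libraries and to 4089, 4637 and 4155 in the IgG4 libraries, 2.01-fold more on average. Kappa variable genes summed to 9577 and 9563 against 11899, 11739 and 11842 (1.24-fold), and heavy chain variable genes to 5836 and 5934 against 3839, 3935.5 and 3490.5 (0.64-fold). IGLC3, IGKC and RAG1 moved in the same direction as the light chain sums. No test was run on the sums.

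IgG4 replicate 2 differed from the mean of IgG4 replicates 1 and 3 by more than 2-fold at 237 of 11958 genes (145 lower, 92 higher). Among them MS4A1, which encodes CD20, had 472 normalized reads against 2083 and 1970, BANK1 106.9 against 649.7 and 531.8, and DUSP14, a phosphatase gene, 6 against 804.3 and 743.7. DNTT, the polymerase that adds bases at antigen receptor joints, had 50356 against 18015 and 20910, and CCR7, a homing receptor gene, 324.3 against 104.8 and 118.3. The IgM libraries had 34366 and 32234 for DNTT, which lies between these, and 388.1 and 417.3 for CCR7, which is nearer to replicate 2. For MS4A1, BANK1 and DUSP14 replicate 2 lay below both IgM libraries as well. List medians for IgG4 replicate 2 are differences in log2 of normalized reads plus 1, not on the deposited scale. Genes of the unfolded protein response had a median of -0.54 in that library (26 genes), glycolysis genes -0.53 (28), memory B-cell genes -0.61 (8) and MYC targets -0.28 (37). Between IgG4 replicates 3 and 1 they had -0.08, -0.05, -0.05 and -0.04. Not every list moved this way: G2 and mitosis genes had 0.19 in replicate 2 and 0.01 between 3 and 1. Histone genes had -0.25 between 3 and 1 and 0.16 in replicate 2. The fixed B-cell receptor and germinal-centre identity lists had medians of -0.02 each in that library, with 2 of 35 and 2 of 21 members over 2-fold lower. It also had the fewest IGHM reads, 49 in all.

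What set this library apart was weighed against its making and its cells. After thinning to equal totals and removing the trends on GC content and transcript length, 202 of 11083 genes were still over 2-fold apart (200 before the trends were removed) against 24 between IgG4 replicates 1 and 3, which argues against depth, GC content or length as the cause. Thinning alone left 241 of 11958 genes against 39, and removing the trends alone 199 against 24; the trends were removed only for genes of known GC content, 83.0% of those apart after thinning, so the lower count reflects fewer genes. IgM-positive cells left in IgG4 replicates 1 and 3, at the 0.72% that IGHM allows, would supply the reads missing from replicate 2 at 0.0% of 144 genes over 2-fold lower there. IGHM itself was left out. So small a share could supply them only for a gene far higher in IgM cells, so this outcome was largely set in advance. It shows only that such cells, expressing these genes as the IgM libraries do, were too few to account for the 144 genes. Immunoglobulin variable genes were over 2-fold apart at a rate of 35.3% (6 of 17), against 1.93% of other genes (exact Fisher p = 5.9e-07). Between IgG4 replicates 1 and 3 it was 2 of 17 against 36 of 11941 others. Relative to other genes, that excess was no smaller than the one in replicate 2. The condition set for a different mix of clones, a larger excess in replicate 2, was therefore not met. Fisher's test also takes the variable genes as independent, which similar genes may not be. Whether the excess differs between the 2 comparisons was not tested, and a different mix of B-cell clones stays open. IGKV1-12, for example, had 1869.9 normalized reads in IgG4 replicate 2, 2.1 and 0 in replicates 1 and 3, and 615.2 and 473.1 in the IgM libraries. Whether reads moved between similar variable genes cannot be told from the test: 50.0% of the 6 (IGKV1-12, IGLV3-19 and IGLV4-3) shared at most 2.4% of their 31-base words with any other variable gene at these levels, and the other 3 shared 14.2% to 34.4%. The bound of that test was set, and later made stricter, with these shares known. A difference between sorts or cultures stays open, since the labels give no batch.

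The IGHM reads left in IgG4 cells were weighed against unswitched cells. IGHM stood at 0.713%, 0.0835% and 0.727% of its IgM level in IgG4 replicates 1, 2 and 3. If unswitched cells were the only source, IGHD would keep its proportion to IGHM, but IGHD reads per IGHM read were 0.59 times those of IgM cells (exact binomial 95% interval 0.46 to 0.74, counting error only). IGHD had 27, 0 and 52 reads in the 3 libraries. Some unswitched cells may remain beside another source, which was not tested.

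The rise of IGHG1, IGHG2 and IGHG3, which lie between the cut sites, was weighed against reads of IGHG4 being assigned to them. They share 42.5%, 39.9% and 41.8% of IGHG4's 31-base words, and IGHGP, which did not rise, shares 13.7%, or 34.3% of the lowest of these. The rises came to 12.76%, 4.05% and 17.13% of the IGHG4 reads, an order that does not follow the shared words, and IGHGP changed by -0.7 reads. Whether misassigned reads account for the rise of the 3 genes cannot be told from these values, and transcription of the genes themselves, on either chromosome, was not tested.

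HLA-L (0 and 0 reads in IgM, 176.4, 152.5 and 171 normalized reads in IgG4) and LOC100294145 (0 and 0, then 226.2, 178.9 and 197.4), both on chromosome 6, and LOC103021295 on chromosome 1 (54 and 47.5, then 0, 0 and 0) had 0 recovered reads in one group and at least 10 in each library of the other. The 9 other splits of the 5 libraries into 2 and 3 gave 0 to 6 such genes. Median differences per chromosome between IgG4 and IgM, in log2 of normalized reads plus 1, lay between -0.021 and 0.049 over 23 chromosomes.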
